A study of Mus musculus with 2 samples.

How the data were processed

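The series holds 2 total RNA sequencing libraries of mouse midbrain at 14.5 days of embryonic development, from the B6NCrl strain. Per the labels, each library came from the midbrain of a single pup, the pups were collected on different days, and the libraries are biological replicates 1 and 2 of the same tissue. They are called embryo 1 and embryo 2 here. The labels also give the sex of each sample as pooled, which is at odds with a single pup, so the sex-linked genes are reported for each library. Per the labels' protocols, RNA longer than 200 nt was extracted with the mirVana method, 10 ng entered each library, ERCC spike-in RNAs were added, and the general protocol is named after SmartSeq, a method for cDNA synthesis from small amounts of RNA. The strand protocol is not given in the sources used here, so overlapping sense and antisense genes cannot be told apart.

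The deposited gene and transcript tables were made from alignments to the mm10 assembly with the GENCODE M4 annotation, per the text record deposited with each sample. The name and version of the quantifier are not given in the sources used here. Expected counts are the authors' estimated reads per gene or transcript, and they need not be whole because a read that fits several places is divided among them. TPM and FPKM values are the authors' own, per the file headers, and the TPM scale was set over all rows of a file, spike-ins included. The deposited percent of a gene's TPM taken by each transcript was not used, since the shares were computed from the deposited TPM of the transcripts. Posterior mean TPM, deposited beside the maximum-likelihood values, entered only as an alternative. A gene's TPM also depends on which of its transcripts were estimated to be present, so a ratio of TPM can differ from a ratio of counts.

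Each gene table had 69691 rows. Of these, 43346 had an Ensembl identifier, 96 were ERCC spike-ins, 1 was the phiX genome and 26248 had only a numeric identifier. Gene symbols, gene types and coordinates came from GENCODE M21, a later annotation of the same mouse assembly (GRCm38, which is mm10), and matched 42462 Ensembl rows (98.0%). The other 884 Ensembl rows kept their identifiers. The numeric rows are not named in the sources used here, held 6 counts in embryo 1 and 14 in embryo 2, and stayed out of library sizes and comparisons, as did the spike-ins.

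With 1 group of 2 libraries there was nothing to test between groups, and a p-value is given nowhere. Levels are means of the deposited TPM with the SD over both embryos (n = 2). A gene was called detected at a TPM of at least 1 in both libraries. Expected counts were rounded to whole numbers and scaled with the TMM method of edgeR. The spread between the embryos was summarised over genes as edgeR's common dispersion, given as the biological coefficient of variation, for genes with at least 10 summed counts. Ratios between the embryos were computed from the unrounded expected counts, scaled by the same factors, with a prior count of 0.5 for log2 values. A fixed rule of size was used for single genes, namely a ratio of at least 2-fold among genes with at least 100 summed counts. The 95% interval of a ratio is an exact conditional binomial interval. It covers counting error only, since reads without molecular identifiers are not independent molecules, and it holds nothing of the variation between animals. Where a gene had 0 counts in a library, the ratio is a lower bound against a floor of 3 counts in that library, written as at least N-fold. This bound leaves out the counting error of the other library. It can exceed the lower limit of the 95% interval, which was 465-fold for Eif2s3y against a bound of 572-fold. A floor of 3 counts amounted to a TPM of 0.157 in each library for a transcript with an effective length of 1 kb.

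In all, 37 gene lists were fixed before the data were examined: 9 regional lists, 19 cell type lists and 9 others. The regional lists covered midbrain and isthmus, dopaminergic neurons, red nucleus and oculomotor neurons, serotonergic neurons, forebrain, thalamus and pretectum, Hox groups 1 to 4, Hox groups 5 to 13, and rhombic lip. The cell type lists covered progenitors, cell cycle, neurogenic factors, immature and later neurons, GABAergic and glutamatergic neurons, astrocytes, precursor and mature oligodendrocytes, and the non-neural types named in the report. The remaining lists covered sex-linked, imprinted, immediate early, hypoxia, mitochondrial, non-polyadenylated, retinoic acid, floor plate and roof plate genes. Several lists shared members with other lists: 9 of 23 for midbrain and isthmus, 5 of 18 for dopaminergic, 2 of 11 for red nucleus and oculomotor, 2 of 18 for forebrain, 4 of 10 for GABAergic, 3 of 7 for oligodendrocyte precursor, 2 of 17 for mesenchyme, 3 of 7 for Schwann and neural crest, 4 of 11 for floor plate and 5 of 18 for roof plate genes. Rhombic lip, progenitor, neurogenic, glutamatergic, mature oligodendrocyte, immediate early and retinoic acid lists shared 1 member each, and the others none. Each list's median TPM was placed among 10000 random lists of the same size drawn from nuclear protein-coding genes. Each list's median log2 ratio was placed among 10000 random lists of the same size matched on mean expression in 20 bins, over members with at least 10 summed counts. These percentiles describe the 2 libraries and are no test. Named genes were each list's key genes with up to 4 further members of the highest mean TPM, the 10 genes with the highest mean TPM apart from mitochondrial ones, the 10 named genes with the largest ratio in each direction, and 16 genes with known splice variants. Where a gene outside this rule is named, the text says that it was chosen after its values were seen. Some genes that the rule names are not reported here.

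The alternatives were DESeq2 size factors, spike-in scaling, TPM ratios, other count and TPM minimums, posterior means, means in place of medians, another background for levels, and each embryo alone. Removal of a trend on transcript length and GC content was added after seeing the data. That trend was a cubic polynomial fitted to genes with at least 100 summed counts, using the longest M21 transcript of each gene. Every named gene had a length and a GC value. The dispersion of the spike-ins alone was also added after seeing the data.

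The calculations were tested on simulated data with the depth of these libraries. For 18910 genes simulated with a coefficient of variation of 20%, 200 of them changed 4-fold, the common dispersion gave 20.1% over the unchanged genes and 22.7% over all. The 2-fold rule found 99% of the changed genes and passed 1.99% of the unchanged ones. Of 100 random lists of 18 genes, 3 fell outside the central 95% with no shift, and 99 fell below it with a log2 shift of 0.5. The 26.7% found between these embryos is pooled over all genes, as is the simulated 22.7%, and changed genes raise such a value. The spread of unchanged genes alone is not known here. The share of them that passes the 2-fold rule can therefore be larger or smaller than in the simulation. Genes were also simulated independently, so the list check does not cover lists whose members vary together. Calculations used R 4.3.3 with edgeR 4.0.16 and DESeq2 1.42.0, and Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and statsmodels 0.14.6.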

Results

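Total RNA was sequenced from the midbrains of 2 mouse embryos at 14.5 days of development, with 1 library per embryo. The midbrain lies between the forebrain and the hindbrain, and at this age it holds dividing progenitors next to newly born neurons. The labels name 1 tissue at 1 age and no treatment, so the design implies a description of the tissue and of how far the 2 biological replicates match. The tables assigned 32.7 × 10⁶ reads to annotated rows in embryo 1 and 30.2 × 10⁶ in embryo 2. ERCC spike-in RNAs took 3.15% and 3.32% of these counts, and mitochondrial genes took 1.93% and 2.58% of the gene counts.

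The most abundant gene transcript was Tuba1a, the main alpha-tubulin of developing neurons, at a TPM of 15786 ± 631 (SD, n = 2, as for all levels written this way). Further leading protein-coding genes were Nnat at 6892 ± 1247, the actin gene Actb at 6832 ± 11.1, the tubulin-binding Stmn1 at 5692 ± 336, the ferritin gene Ftl1 at 5039 ± 393 and Tmsb10 at 5034 ± 633. Mitochondrial genes, some of which were more abundant, are counted apart from this top 10. Its remaining places went to transcripts that share sequence with other copies. They were Gm42418 at 11520 ± 87.6, the mitochondrial-like pseudogene Gm28437 at 11125 ± 1208, and the signal recognition particle RNAs Rn7s1 and Rn7s2, whose reads the counting could not assign to a single copy. The leading mitochondrial mRNAs were mt-Atp8 at 7619 ± 511, mt-Atp6 at 6472 ± 267 and mt-Cytb at 4412 ± 181. Reads of mitochondrial genes could have been assigned to Gm28437, which was not tested. The levels, shares and ratios given for mitochondrial genes, and their order, carry this limit. Protein-coding nuclear genes made up 78.5% of TPM in embryo 1 and 76.2% in embryo 2, and lincRNA genes made up 2.24% and 2.36%. Gm42418 is annotated as a lincRNA, and its TPM of 11582 and 11458 formed a large part of the lincRNA share. A TPM of at least 1 in both embryos was reached by 14565 genes, of which 12786 were protein-coding.

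Most genes had similar levels in the 2 embryos. Across the 16065 genes at a TPM of at least 1 in either library, Pearson's r of log2(TPM + 1) was 0.969 and Spearman's rho was 0.970, although genes are not independent replicates. Among 14011 genes with at least 100 summed counts, 95.2% lay within 2-fold and 85.8% within 1.5-fold of each other. The median absolute log2 ratio was 0.231 for these genes and 0.083 for the 48 spike-ins with at least 100 summed counts. The 2 sets were not matched on counts, so part of this gap can be counting error. Pooled over 18910 genes, the coefficient of variation between the embryos was 26.7%, and over 71 spike-ins it was 3.55%. The spike-ins do not pass through dissection or extraction of the tissue, so they do not measure the whole technical spread. Of the 96 spike-ins, 84 were detected in both libraries.

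**Figure D1:**
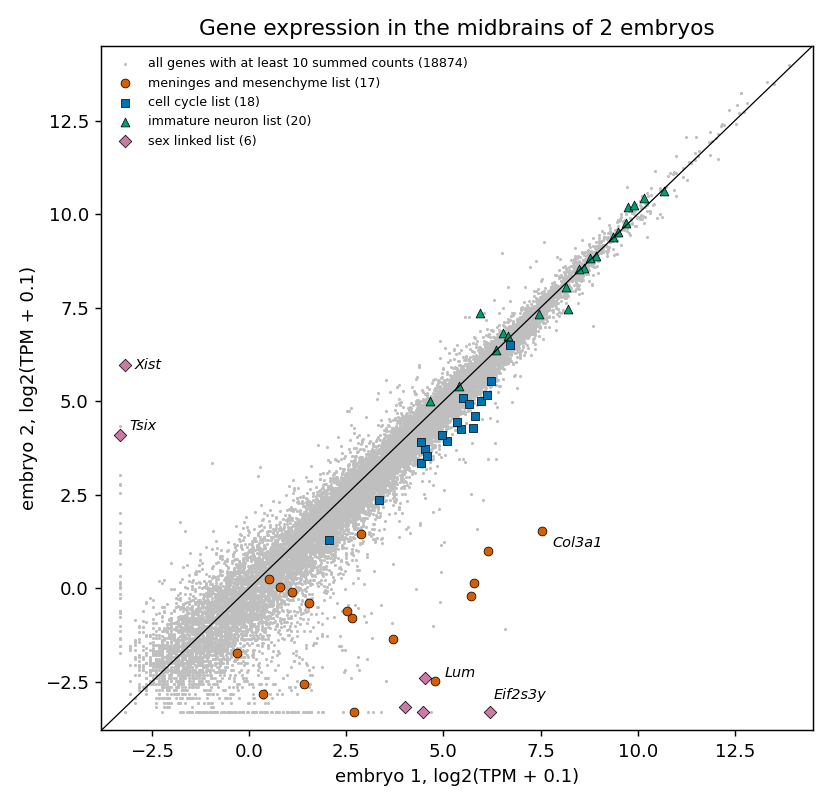
Expression of each gene with at least 10 summed counts in embryo 1 (x axis) and embryo 2 (y axis), both as log2(TPM + 0.1), with the line of equal values. Members of the mesenchyme list, such as Col3a1 at a TPM of 187 in embryo 1 and 2.81 in embryo 2, and the sex-linked genes lie far from the line, while the cell cycle genes lie on or below it and most immature neuron genes on it.

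Genes that mark the midbrain and its border with the hindbrain were expressed in both embryos, while Hox genes, which mark more posterior levels, were at or near 0. Of 23 midbrain and isthmus genes, 22 reached a TPM of 1 in both embryos, and the median of the list (11.9) lay above 87.3% of random lists of protein-coding genes, though above only 18.7% of random lists of genes at a TPM of at least 1. Otx2, the homeobox gene that specifies forebrain and midbrain, stood at 88.1 ± 16.7, Gata3 at 83.1 ± 19.6, Meis2 at 66.6 ± 2.91, Cnpy1 at 66.1 ± 19.2, Pou4f1 at 64.4 ± 25.1 and En1, the engrailed gene of the midbrain-hindbrain boundary, at 13.9 ± 0.559. Otx2 lies on chromosome 14 at 48657677 to 48673819 and En1 on chromosome 1 at 120602418 to 120607992 (GRCm38). The dopaminergic list had a median of 5.45, above 54.6% and 0.60% of the same random lists, with 17 of 18 members at a TPM of 1 or more, among them Th, the rate-limiting enzyme of dopamine synthesis, at 23.8 ± 4.15 and the transcription factor Nr4a2 at 21.8 ± 4.52. Further members were Ddc at 19.9 ± 1.12, the vesicular transporter Slc18a2 at 16.4 ± 2.57, En1, which the midbrain and isthmus list also holds, and Aldh1a1 at 8.21 ± 0.728. Serotonergic genes were lower, with a median of 2.10 and Tph2, the neuronal serotonin-synthesising enzyme, at 6.13 ± 0.778. Red nucleus and oculomotor genes had a median of 1.85 but a wide range. Pou4f1, which the midbrain and isthmus list also holds, was the highest at 64.4 ± 25.1, followed by Six3 at 15.9 ± 0.156. Isl1 stood at 5.33 ± 1.41 and Phox2a at 0.625 ± 0.0495.

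Of the neighbouring regions, the thalamus and pretectum list was the most highly expressed, with a median of 20.7 and 10 of 11 members at a TPM of 1 or more. It was led by Tcf7l2 at 581 ± 36.6 and Lhx9 at 94.0 ± 9.71, and its key gene Gbx2 stood at 9.54 ± 0.516. Several of these genes are also active in the midbrain itself, so the list does not mark the diencephalon alone. Forebrain genes had a median of 0.425, above 6.08% of random lists, and only 3 of 18 reached a TPM of 1 in both embryos, namely Neurod6 at 16.1 ± 2.12, Emx2 at 15.5 in embryo 1 and 14.6 in embryo 2 and Eomes at 1.41 ± 0.156. None of the 12 genes of Hox groups 1 to 4 reached a TPM of 1, and 7 of them had 0 counts in both embryos. Among the 27 genes of Hox groups 5 to 13, 22 had 0 counts in both, including Hoxb8. A count of 0 allows a TPM of up to 0.157 for an effective length of 1 kb. The rhombic lip list had a median of 4.53 over 9 members, with Pax6 at 17.2 ± 1.61, Zic1 at 14.4 ± 0.106 and Atoh1 at 3.54 ± 0.148.

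**Figure D2:**
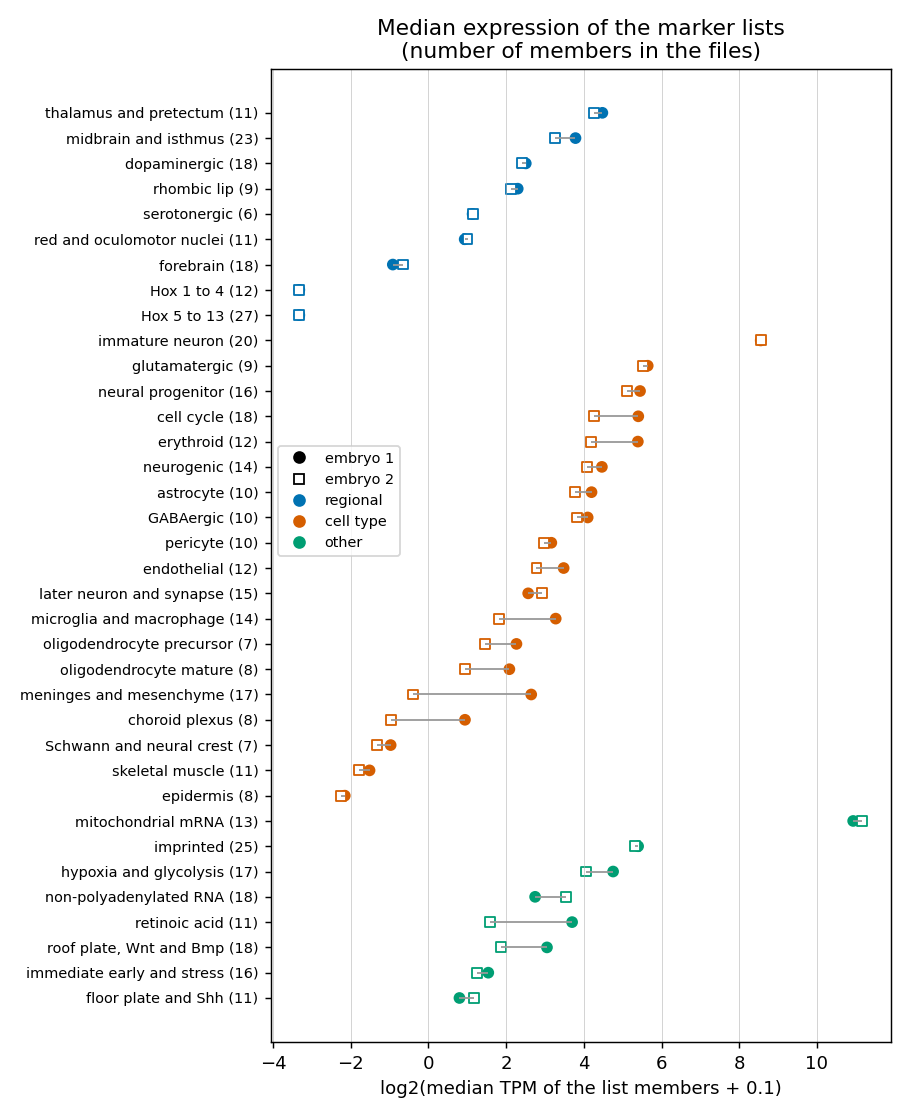
Median TPM of the members of each marker list in embryo 1 (filled circles) and embryo 2 (open squares), as log2(median TPM + 0.1), with the number of members in parentheses and the sex-linked list left out. The immature neuron list has medians of 375 and 376, both Hox lists have a median of 0, and the mesenchyme list has medians of 6.16 and 0.66.

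Genes of young neurons dominated the neural lists. All 20 immature neuron genes exceeded a TPM of 10 in both embryos, and their median was 376. Tubb3, the neuronal beta-tubulin, stood at 1612 ± 36.8, the growth cone gene Gap43 at 1263 ± 160, Stmn3 at 1079 ± 180, Stmn2 at 1018 ± 226 and the migration gene Dcx at 236 ± 85.0. All 16 progenitor genes were detected, with a median of 39.0, led by Fabp7 at 1362 ± 210 and Vim at 424 ± 110, with Sox2 at 13.8 ± 2.68. The cell cycle list had a median of 31.3 (42.2 in embryo 1 and 19.2 in embryo 2) with all 18 members detected, and the neurogenic list one of 19.3 with all 14 detected, led by Hes6 at 159 ± 18.8. Both transmitter classes were present. The GABAergic list had a median of 15.2, with the glutamate decarboxylases Gad1 at 86.9 in each embryo and Gad2 at 46.5 ± 1.48. The glutamatergic list had a median of 47.8, with the vesicular transporter Slc17a6 at 77.1 ± 5.14. Genes of later neurons and synapses were less abundant, with a median of 6.68 and Camk2a at 7.65 ± 0.778.

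Glial genes were mixed in level. Gfap, the intermediate filament of mature astrocytes, had 10 counts in embryo 1 and 0 in embryo 2, where the floor is a TPM of 0.0887. In contrast, Sparcl1 stood at 91.9 ± 16.3, Aldoc at 64.4 ± 8.92 and Aldh1l1 at 38.1 ± 2.60, and the astrocyte list had a median of 17.6. Oligodendrocyte precursor genes had a median of 4.94 over the mean levels, but 4.71 in embryo 1 and 2.63 in embryo 2, with Olig1 at 40.0 ± 6.68 and Olig2 at 5.52 ± 1.15. These medians can rest on different members in each embryo and do not show the direction of the list. By ratios of scaled counts, 6 of the 7 precursor genes were higher in embryo 2, and the mature list had a median log2 ratio of only -0.05. Mature oligodendrocyte genes had a median of 3.91, with 4.14 in embryo 1 and 1.83 in embryo 2. Cnp stood at 21.2 ± 1.73 and the myelin gene Mbp at 12.8 ± 1.57. Cldn11, the only member over 2-fold, stood at 30.0 in embryo 1 and 0.68 in embryo 2, a 39.9-fold difference (26.5 to 63.3). The mean log2 ratio of the mature list was -0.75. Mobp and Opalin, named because they alone of the list had 0 counts in both embryos, were chosen after their values were seen.

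Among non-neural lists the erythroid genes were highest. Their median was 30.0 (41.8 in embryo 1 and 18.1 in embryo 2), with the haemoglobin genes Hba-a2 at 3566 ± 1001 and Hbb-bs at 1737 ± 416, and reads of the near-identical Hba-a1 and Hba-a2 could not be assigned to a single copy. Medians were 8.89 for endothelial genes, with Cldn5 at 63.9 ± 9.87, and 9.01 for pericyte genes, with Vtn at 70.1 ± 54.5 and Pdgfrb at 10.3 ± 4.45. Microglia and macrophage genes had medians of 9.59 in embryo 1 and 3.40 in embryo 2, and mesenchyme genes 6.16 and 0.66. Choroid plexus genes had a median of 1.28 (1.82 in embryo 1 and 0.415 in embryo 2), Schwann and neural crest genes 0.355, skeletal muscle genes 0.22 and epidermal genes 0.117. Krt5 had 0 counts in both embryos, whereas Krt10 stood at 9.31 ± 0.212 and Krt1 at 5.79 ± 1.87.

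Most genes of the imprinted list were abundant, with a median of 40.6 over 25 genes, above all 10000 random lists of protein-coding genes. The median also lay above 99.1% of random lists of genes at a TPM of at least 1. Nnat led, followed by Meg3 at 1271 ± 603, Ndn at 1206 ± 66.7 and Gnas at 1165 ± 3.08. Hypoxia and glycolysis genes had a median of 21.7, with Eno1 at 762 ± 5.46 and Vegfa at 3.21 ± 0.728. Immediate early and stress genes had a median of 2.70, with Fos at 0.915 ± 0.0495. The medians of the remaining lists were 2081 for mitochondrial mRNAs, 9.11 for non-polyadenylated RNAs, 6.58 for retinoic acid genes (12.9 in embryo 1 and 2.90 in embryo 2), 6.10 for roof plate, Wnt and Bmp genes (8.19 and 3.54), and 1.81 for floor plate and Shh genes. Rn7sk, a non-polyadenylated regulatory RNA, was present at 736 ± 315.

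The sex-linked genes separated the embryos completely. Xist, the RNA made from the inactive X chromosome of females, had 3 counts in embryo 1 and a TPM of 62.0 in embryo 2 (chromosome X, 103460366 to 103483254). In contrast, Eif2s3y on chromosome Y (1010543 to 1028847) had a TPM of 73.0 in embryo 1 and 0 counts in embryo 2, at least 572-fold higher, where the floor is a TPM of 0.134. Ddx3y had a TPM of 22.3 in embryo 1 and 0 counts in embryo 2, at least 513-fold higher. Kdm5d and Uty had TPM values of 23.0 and 16.1 in embryo 1 and 1 count each in embryo 2. Kdm5d was 1387-fold higher (95% counting interval 249 to 54826), and the interval for Uty was 175 to 38535-fold. Ratios against 1 count cannot be ranked against the lower bounds above, which use a floor of 3 counts. Tsix, which is antisense to Xist and overlaps it, had 0 counts in embryo 1 and a TPM of 16.9 in embryo 2, but reads of the 2 genes cannot be told apart without strand. Usp9y and Zfy2 had 0 counts in both embryos.

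Genes of connective tissue, macrophages, vessels and blood were higher in embryo 1. Each of the 17 mesenchyme genes was higher there, 15 of them by over 2-fold, and the median ratio was 22.1-fold (median log2 ratio of embryo 2 over embryo 1 -4.46, against -0.28 to 0.23 for the central 95% of matched random lists). Col3a1, a fibrillar collagen on chromosome 1 (45311538 to 45349706), was 69.6-fold higher (60.1 to 81.0), Col1a1 94.3-fold (72.4 to 125), the matrix proteoglycan gene Dcn 50.4-fold (35.9 to 72.9) and Lum, with 3 counts in embryo 2, 314-fold (107 to 1525). All 14 microglia and macrophage genes were higher in embryo 1, by a median of 2.35-fold, including Csf1r, the receptor that these cells need, at 2.79-fold (2.46 to 3.16) and Lyz2 at 5.94-fold (4.75 to 7.50). The 11 erythroid genes that could be compared were higher by a median of 1.82-fold, with the embryonic globin gene Hbb-y at 3.21-fold (3.02 to 3.41) and the adult-type Hbb-bs at 1.27-fold (1.24 to 1.29). All 12 endothelial genes were higher by a median of 1.55-fold, with Kdr at 2.72-fold (2.51 to 2.95). Of 8 choroid plexus genes 7 were higher in embryo 1, by a median of 1.58-fold, led by the transthyretin gene Ttr at 233-fold (118 to 541), but over the 4 of these genes with at least 100 summed counts the list lay inside the random range. Pericyte genes had a median log2 ratio of -0.29, inside the random range of -0.32 to 0.28.

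Cell cycle genes were higher in embryo 1 and genes of young neurons slightly higher in embryo 2. All 18 cell cycle genes were higher in embryo 1, by a median of 1.70-fold (median log2 ratio -0.76, random range -0.17 to 0.17). The proliferation marker Mki67 was 1.83-fold higher (1.69 to 1.98) and the mitotic kinase gene Cdk1 1.60-fold (1.45 to 1.76), whereas Pcna differed by 1.03-fold (0.976 to 1.09). The 4 members over 2-fold, chosen after their values were seen, were Top2a, Ccna2, Ccnb1 and Ccnb2. Neurogenic genes were higher in embryo 1 in 10 of 14 cases, by a median of 1.36-fold, although with a mean in place of the median the list lay inside the random range. The immature neuron list moved the other way in 17 of 20 genes, by a median of 1.15-fold (log2 ratio 0.20, random range -0.12 to 0.16), and with TPM ratios, which put the median of all genes at -0.13, the list stood at 0.043. Stmn2 was 1.53-fold higher in embryo 2 (1.51 to 1.55), while Dcx was 1.25-fold higher in embryo 1 (1.23 to 1.27). Later neuron and synapse genes were higher in embryo 2 in 12 of 14 cases, by a median of 1.22-fold. The progenitor list had a median log2 ratio of -0.06, inside its random range, but -0.18 and outside after removal of a trend with transcript length and GC content.

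**Figure D3:**
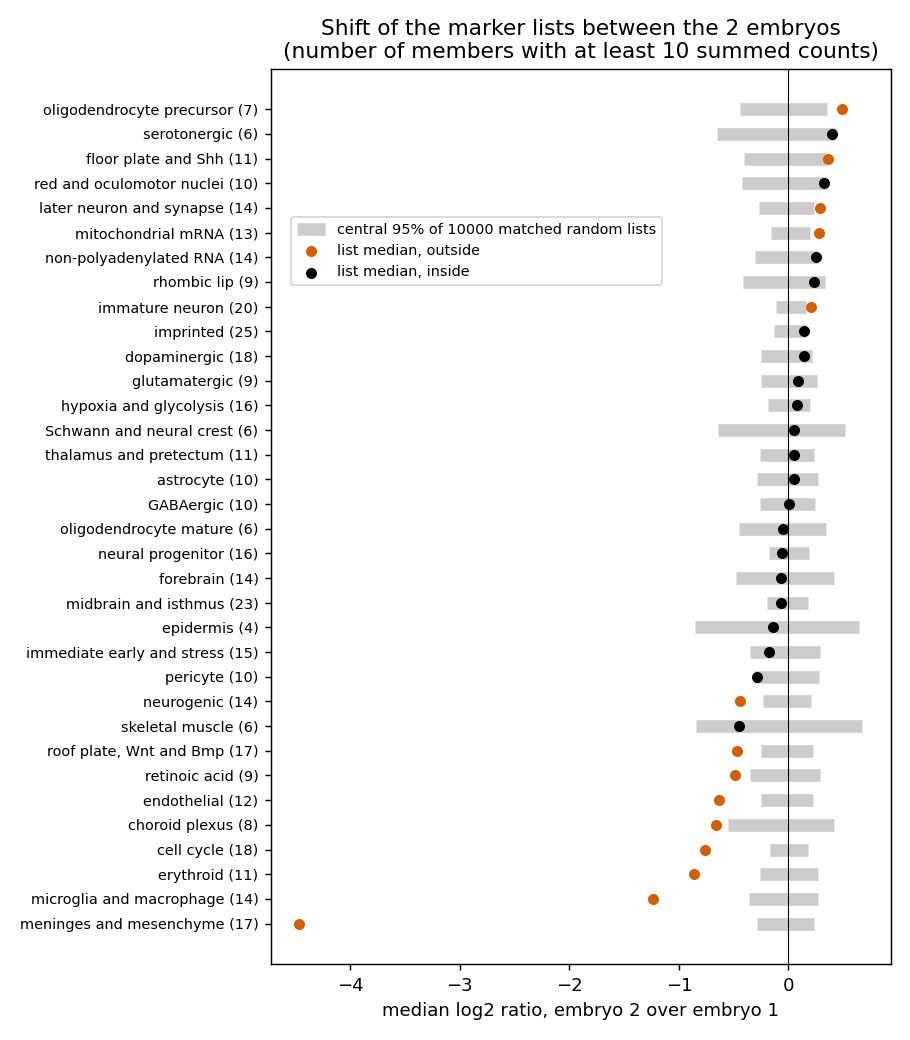
Median log2 ratio of each list, embryo 2 over embryo 1 (points, red where outside), against the central 95% of 10000 random lists of the same size matched on expression (grey bars), with the sex-linked list left out and the number of members used in parentheses. The mesenchyme list at -4.46 and the microglia and macrophage list at -1.23 lie farthest to the left, and the oligodendrocyte precursor list at 0.49 farthest to the right.

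The regional lists that could be compared stayed inside their random ranges, although single members differed, such as Pou4f1 at 1.52-fold (1.43 to 1.60) higher in embryo 1. The median log2 ratio was -0.07 for midbrain and isthmus genes, 0.14 for dopaminergic, 0.39 for serotonergic, 0.33 for red nucleus and oculomotor, -0.06 for forebrain, 0.05 for thalamus and pretectum and 0.23 for rhombic lip genes. Some of these calls depended on the processing. After removal of the length and GC trend the dopaminergic list (0.23) and the serotonergic list (0.46) lay outside, and with means over members the dopaminergic (0.21) and rhombic lip (0.35) lists did. The Hox lists had too few counts to be compared. GABAergic genes had a median log2 ratio of 0.00, glutamatergic genes 0.09 and mature oligodendrocyte genes -0.05, also inside. Of the signalling lists, 13 of 17 roof plate, Wnt and Bmp genes were higher in embryo 1, by a median of 1.38-fold, with Wnt1, which the midbrain and isthmus list also holds, at 2.93-fold (2.08 to 4.21). Retinoic acid genes were higher in embryo 1 in 7 of 9 cases, by a median of 1.40-fold, with Rarb at 2.00-fold (1.66 to 2.42), and this list shares Aldh1a2 with the mesenchyme list. Floor plate and Shh genes were higher in embryo 2 in 8 of 11 cases, by a median of 1.28-fold, with Shh at 23 and 75 counts, but fell inside the random range at a minimum of 100 counts and after removal of the trend. Oligodendrocyte precursor genes were higher in embryo 2 in 6 of 7 cases, by a median of 1.40-fold, the exception being Pdgfra, which the mesenchyme list also holds, but after removal of the trend the median log2 ratio fell from 0.49 to 0.26, inside the random range. Mitochondrial mRNAs were higher in embryo 2 in 12 of 13 cases, by a median of 1.22-fold, with mt-Co1 at 1.62-fold (1.61 to 1.63), but removal of the trend took the median log2 ratio from 0.28 to 0.12, inside the random range.

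The other lists stayed inside their random ranges, with median log2 ratios of 0.14 for imprinted, -0.18 for immediate early, 0.08 for hypoxia, 0.26 for non-polyadenylated, 0.05 for astrocyte, 0.05 for Schwann and neural crest, -0.45 for muscle and -0.14 for epidermal genes. Under other settings 3 of these lists lay outside: astrocyte genes with means over members (-1.14), imprinted genes at a minimum of 100 counts (0.18), and non-polyadenylated RNAs at 100 counts (0.73), with means (0.58) or without a count filter. Within them, Igf2 was 5.05-fold higher in embryo 1 (4.52 to 5.66) and Meg3 1.88-fold higher in embryo 2 (1.85 to 1.90), and the gap junction gene Gja1 was 5.97-fold higher in embryo 1 (5.48 to 6.50). In total, 15 of 35 lists lay outside the central 95%, 10 with lower and 5 with higher values in embryo 2. The sex-linked list counts among the 10, although 2 of its 6 members were higher in embryo 2. If the members of a list varied independently, 1.75 lists would be outside by chance. Members of a list can vary together, so more lists than this could lie outside by chance. After removal of the trend 15 lists also lay outside, 12 of them the same: the oligodendrocyte precursor, mitochondrial and floor plate lists were lost and the dopaminergic, serotonergic and progenitor lists gained.

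Single genes differed in both directions. Of 14011 genes with at least 100 summed counts, 470 were over 2-fold higher in embryo 1 and 200 in embryo 2. Hence 29.9% of the differing genes were higher in embryo 2, against 19.1% with spike-in scaling and 16.7% with TPM ratios. Those 2 scales also moved the median log2 ratio of all these genes, to -0.11 and -0.13. Of the 470 genes, 52 belonged to a list, most often to the mesenchyme list (13 of the 13 members with enough counts). With a prior count of 0.5, the largest log2 ratios in this direction belonged to the Y-linked genes, Lum, the meningeal and kidney anion transporter gene Slc22a6 (479 and 0 counts, at least 144-fold), the connexin gene Gjb2 (400 and 0, at least 120-fold), the lymphatic and macrophage receptor gene Lyve1 (138 and 0, at least 41.5-fold), the pseudogene Gm13370 within Pnpla7 (at least 56.3-fold) and Gm14440, a member of a repeated family (at least 50.9-fold). In the other direction the largest log2 ratios, after Xist (7685-fold, 2629 to 37269) and Tsix, belonged to Gm37676 within Nucks1 (at least 58.0-fold), Gm14288 (at least 52.6-fold), the pseudogene Gm10359 (9.25-fold), Duxbl3 (7.34-fold), Gm14434 (5.38-fold) and the noncoding BC051226 (5.29-fold). Gm14288, Gm14434 and Gm14440 belong to 1 family of similar genes on chromosome 2, so their reads could be exchanged between copies. Rac3, a small GTPase gene of developing neurons on chromosome 11 (120721470 to 120723969), was 6.25-fold higher in embryo 2 (5.92 to 6.60), at a TPM of 90.2 and 501, and Prr7 was 5.26-fold higher (4.37 to 6.38). No annotated gene overlaps Rac3 or Prr7. Among abundant genes chosen after their values were seen, Trappc3, Raly and Arpc3 were 3.59-fold, 3.48-fold and 3.45-fold higher in embryo 2, and the log2 ratio of Stmn4 was 1.59. Ratios also followed transcript features. Across 12920 protein-coding genes, Spearman's rho of the log2 ratio was -0.257 with transcript length and 0.241 with GC content, and across 48 spike-ins it was -0.449 with length. After removal of that trend the log2 ratio of Rac3 was 2.32 in place of 2.64.

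Most genes chosen for their known splice variants used the same leading transcript in both embryos, 12 of the 15 with several transcripts, and in 8 of the 15 that transcript took over 50% of the gene's TPM in each embryo. The leading transcript of Pkm, Pkm-202, took 58.2% and 69.2% of the gene in embryos 1 and 2, with the rest on Pkm-201. Snap25-201 took 91.8% ± 1.86 of Snap25, Clta-204 74.9% ± 4.41 of Clta, Rbfox1-202 73.1% ± 3.76 of Rbfox1 and Cdc42-201 58.0% ± 6.10 of Cdc42. For the cell adhesion genes, Ncam1-204 took 63.6% ± 7.68 of Ncam1 and Nrcam-201 63.4% ± 8.24 of Nrcam. On average Dclk1-201 took 51.9%, Numb-204 50.7%, Map2-201 48.9% and Tpm1-209 42.7% of their genes. The 59.2% of Gad1 in each embryo lay on Gad1-206, annotated as a processed transcript without a coding sequence, and Ptbp2, left out of these tallies, had a single transcript. The leading transcript differed between the embryos for Mapt, Gria2 and Ank3, where the top 2 transcripts had close shares, 39.8% and 38.5% on average for Mapt. Shares of transcripts that overlap in most exons rest on few distinguishing reads, and the pair of embryos gives no measure of that uncertainty.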

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

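Both checks in this part were chosen only after the files had been seen, and neither was tested against an explanation. Entries with a numeric identifier, which the sources used here do not name and the comparisons leave out, held 6 reads in embryo 1 and 14 in embryo 2, spread over 5 and 9 of 26248 entries. These sums cannot be set against the 3-read floor of a single gene, and whether any entry carries a signal was not tested. Ensembl entries without a gene name held 0.1753% and 0.1671% of the gene reads; they were counted among all genes, but belong to no list and are not named in the report.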

How the results depend on the processing

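Each list outside its random range kept its direction under all settings, while lists inside with medians near 0 changed sign under some: with TPM ratios the thalamus and pretectum list went to -0.10, glutamatergic to -0.13 and hypoxia to -0.08, and with means imprinted genes to -0.03 and astrocyte genes to -1.14. Level percentiles depended on the background: with genes at a TPM of at least 1 in place of all protein-coding genes, 32 of 37 moved. Removal of the length and GC trend and the spike-ins taken alone were chosen only after the results were seen, the other settings before. With TPM taken over protein-coding genes, which raises every value by construction, the median rose to 15.3 for midbrain and isthmus, 7.05 for dopaminergic and 0.552 for forebrain genes. Means of log2 values, which are geometric means over members in place of medians, gave 5.76 for dopaminergic, 0.529 for forebrain and 0.0315 for Hox 1 to 4 genes. Posterior means gave 0.5375 for forebrain and 0.1125 for Hox 1 to 4 genes, and single embryos 0.43 to 0.54 for forebrain genes. With TPM ratios the median log2 ratio of cell cycle genes was -0.91 and that of immature neuron genes 0.043, both still outside their random ranges, and 120 genes were over 2-fold higher in embryo 2. Genes over 2-fold higher in embryos 1 and 2 numbered 1281 and 827 at a minimum of 10 counts, 98 and 70 at 1000 counts, 1199 and 791 at 1.5-fold, and 277 and 92 with the whole counting interval beyond 2-fold, since each setting admits more or fewer genes. The correlation between embryos was 0.932 with a pseudocount of 0.1, 0.983 without a filter, 0.974 for FPKM and 0.976 for protein-coding genes. The coefficient of variation was 24.1% at 100 counts and 3.55% for spike-ins. Protein-coding genes took 90.6% and 89.2% of counts, and the correlation of spike-ins was 0.984 for counts. Among list shifts, 9 passed out of their random range and 6 into it in the same direction, and 8 others moved by over 0.5 times the width of a bootstrap interval over members. The other 220 include most of the sign changes above and the astrocyte value, which lies outside its range. Except where the setting itself shows it, the cause was not tested.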

Other observations

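The globin comparison in this part, and the test on the neurogenic list, were chosen only after the results were seen; the trend tests were written after the raw list values but before the corrected ones. Embryonic globins took a larger share of the globin reads in embryo 1. The embryonic beta-like genes held 11.3% of beta-like globin counts there (4996 of 44212) and 5.06% in embryo 2 (1403 of 27730). For alpha-like globins the shares were 1.58% (Wilson interval 1.47 to 1.69) and 0.872% (0.779 to 0.976). The interval covers counting error only and treats reads as independent, with 1 library per embryo, so it says nothing of the variation between animals. A share within the globins does not depend on how much blood a sample held.

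The sex-linked genes were weighed against the labels, which name a single pup and yet a pooled sex. Xist in embryo 1 stood at 0.0130% of its level in embryo 2 (at most 0.0380%), and the Y-linked genes in embryo 2 at 0.0356% of their level in embryo 1 (at most 0.129%). A library from tissue of both sexes would hold both at a TPM of 1 or more, so it is excluded for each. The values fit 1 male and 1 female embryo, which means that sex and embryo cannot be separated in any ratio given here. The pups were also collected on different days, with 1 library each. Collection day and library preparation therefore cannot be separated from embryo either.

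For the mesenchyme, vessel and blood genes, a different amount of adhering non-neural tissue fits its prediction, because these lists moved the same way and the mesenchyme median was -4.46. That direction is the pattern to be explained, so it does not single out this explanation. The sizes also differed, with medians of 22.1-fold for mesenchyme, 1.82-fold for erythroid and 1.55-fold for endothelial genes, and pericyte genes stayed inside their random range. The fitted trend with transcript length and GC content did not account for this shift, since the mesenchyme median was -4.69 after its removal. Over length deciles the median log2 ratio ran only from -0.11 to 0.23. Removal of so small a trend could hardly have given another outcome, so it was a weak test. No biological explanation was tested, because the design gives no group.

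For cell cycle against neuron genes, different developmental progress may explain the opposite directions, with immature neuron genes at 0.20 against cell cycle genes. The fitted length and GC trend did not account for the cell cycle shift, whose median was -0.65 after its removal. That trend was again small beside the raw median of -0.76, so this too was a weak test. Proliferating cells of adhering tissue could not be told apart from different developmental progress, as the neurogenic median of -0.44 lay between the 2 predictions. Different dissection borders could not be decided, with the largest shift among 3 neighbouring-region lists at 0.23.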
